A study of Mus musculus with 32 samples.

How the data were processed

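Bone marrow of 8 mice was sorted into LSK, CMP, GMP and MEP cells, 1 library per mouse and population. Per the labels' protocols the cells were sorted into TRIzol and libraries were made with the NEBNext Single Cell/Low Input kit for Illumina. The 4 control mice were Mx1-Cre-negative and the other 4 Mx1-Cre-positive, all with floxed Cxadr alleles. STAR, DESeq2, GRCm38 and mm10 are named in the submitters' processing notes, while the read counter and the annotation release are not given in the sources used here. The labels number the mice 1 to 4 within each genotype, and the same number stands for different animals in control and Cxadr-ko. The animal identifiers set mouse 1 of each genotype apart from the others, which was treated as a possible cohort.

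The deposited signal values were gene counts that the authors had divided by 1 size factor per library. This was checked on the values themselves. In each library every value above 0 was a whole multiple of the same step, 0.814 to 1.28 normalized counts, and 100% of 765992 values lay within 0.001 reads of a whole number of reads (largest deviation 6.4e-10). The steps nearest to 1, 0.992 in CMP Cxadr-ko mouse 2 and 0.989 in MEP control mouse 2, passed the same test. The libraries held 8313300 to 13641248 reads. Whole reads were recovered with these steps for the total reads per library, for Poisson intervals and for edgeR and DESeq2. The table held 55487 genes. Exact 95% Poisson intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries of 1 group differed by more than counting error (chi-square over its degrees of freedom 6.76 to 107 in 48 pairs), so the spread between mice was used for every test.

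Each genotype comparison was fitted with limma 3.58.1 in R 4.3.3 (trend on mean level, two-sided) on log2 of the normalized count plus 1, within 1 population at a time (4 against 4 mice). Genes with a value of at least 10 in at least 4 of the fitted libraries were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. For the mean over populations each mouse entered as the mean of its 4 log2 values. In edgeR and DESeq2 the reads of its 4 libraries were summed instead, so gates with more reads of a gene weigh more. Whether the genotype difference varied between populations was tested with the limma F test of the genotype by population terms over 32 libraries with the mouse as a fixed block. The populations were compared in the 16 libraries of the control mice, each against the mean of the other gates, with the mouse as a fixed block. Cxadr was also compared with exact permutation tests. Xist was at least 2294 in every library and 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to at most 8 reads, so no term for sex was fitted.

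Before the data were examined, 28 gene lists (581 genes, 1 symbol without a match) were fixed. They hold stem and multipotent progenitor, granulocyte-monocyte, erythroid, megakaryocyte, lymphoid progenitor and mature cell genes, and genes of pathways such as interferon and NF-kB response, adhesion, cell cycle, ribosome, respiration and lipid synthesis. Of these 26 were tested between genotypes, in each population where at least 5 members passed the filter. The macrophage list had too few members for this, and the sex-linked list was not tested. limma's camera was run with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 100 tests. Camera with an estimated correlation and fry, whose p tests whether the members move 1 way on balance, stand beside it. Members were also adjusted over the list alone.

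Genes were named by a rule also fixed before the data were examined. It takes Cxadr, all called genes where there are at most 24, the genes of lowest p up to 10 in all, and of each list up to 4 called members or, where there are none, up to 2 of lowest p. For the populations it takes up to 8 list members per gate with the largest difference. Within these limits the genes printed were chosen after their values were seen, and some results are not reported here. Mpo, Cd34, Klf1 and Gata1 in the account of the MEP gate fall outside the rule and were chosen after their values were seen, as was the direct comparison of each pair of gates.

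The tests were run on simulated data, libraries drawn with spread between replicates and known changes. At 2-fold changes 70.1% were recovered in LSK, 73.1% in CMP, 71.6% in GMP and 47.8% in MEP, 97.0% in the mean over populations and 46.3% for the difference between populations. At 4-fold changes 89.4% to 98.5% were recovered within single populations, and 2 to 12 unchanged genes were called per comparison. Of 20 simulated gene sets the raised one was called by camera and 0 of the others. The simulated genes varied independently of each other, so this does not show how camera behaves where the genes of a list vary together. The simulated libraries were also drawn independently, with no effect shared by the libraries of a mouse. The recovery in the mean over populations may therefore be too high for real mice, whose libraries can vary together. Changed genes were drawn from the more abundant genes only, so recovery at low counts was not measured.

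The alternatives planned before the data were examined were pseudocounts of 0.5 and 8, no filter and a minimum of 50, TMM and quantile scaling, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, robust variance, sex-linked genes left out, the mouse number as a block, a cohort term for mouse 1, library weights, 1 fit of all 32 libraries, other forms of the mouse block, the Cxadr-ko mice for the population comparison, and each mouse left out in turn. Leaving out mouse 1 of both genotypes and correcting for transcript length were added after the data had been seen. Shared sequence was measured as the share of 50-base words of the annotated transcripts of 1 gene that occur in those of another. The 35 splits of the 8 mice into 4 and 4, and 100 permutations of the gates within mice, were fitted in the same way as the real groups. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.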

Results

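Gene expression was measured by RNA sequencing in 4 progenitor populations sorted from the bone marrow of 8 mice. The mice carried a floxed Cxadr gene, which encodes the coxsackievirus and adenovirus receptor, a cell adhesion molecule of tight junctions. In 4 of them Cxadr was targeted with Mx1-Cre, a recombinase driven by an interferon-inducible promoter, and the 4 control mice lacked Cre. From each mouse the LSK (lineage-negative, Sca-1-positive, Kit-positive stem and multipotent progenitor cells), CMP (common myeloid progenitors), GMP (granulocyte-monocyte progenitors) and MEP (megakaryocyte-erythroid progenitors) gates were sorted, giving 32 libraries in 8 groups of 4. The libraries held 8313300 to 13641248 gene-assigned reads each, recovered from the deposited normalized counts of 55487 genes. In these values 1 read stood for 0.814 to 1.28 normalized counts.

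The first question was whether Cxadr itself (ENSMUSG00000022865, chromosome 16, 78301489 to 78359774, mm10, protein coding) was lower where it was targeted. Cxadr was scarcely transcribed in any population, and its level did not differ between the genotypes by more than the spread between mice. In LSK the normalized count was 28.7 ± 14.7 (SD, n = 4) in control and 30.5 ± 18.1 (SD, n = 4) in Cxadr-ko libraries (exact permutation test, two-sided p = 0.857). In CMP it was 23.5 ± 6.61 and 29.6 ± 12.005 (exact permutation p = 0.4), in GMP 26.3 ± 11.9 and 17.2 ± 3.54 (exact permutation p = 0.229). In MEP it was 12.9 ± 9.97 and 6.10 ± 6.73 (exact permutation p = 0.343), each with n = 4 per genotype. Averaged over the populations of each mouse it was 22.8 ± 2.98 in control and 20.8 ± 1.498 in Cxadr-ko mice (exact permutation p = 0.314, n = 4 each). The smallest p that 4 against 4 mice allow is 0.0286.

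The single control libraries held 22.2, 23.3, 18.7 and 50.5 normalized Cxadr counts in LSK, 18.6, 27.4, 17.2 and 30.7 in CMP, 33.4, 21.3, 38.4 and 11.99 in GMP, and 6.67, 27.7, 7.09 and 10.3 in MEP, for mice 1 to 4. The Cxadr-ko libraries held 22.4, 32.8, 54.5 and 12.3 in LSK, 38.7, 25.8, 14.2 and 39.5 in CMP, 12.4, 20.9, 18.0 and 17.6 in GMP, and 15.5, 2.94, 0 and 5.95 in MEP. Summed over its 4 libraries, a group had between 25 Cxadr reads (MEP, Cxadr-ko; exact 95% Poisson interval 16.2 to 36.9) and 133 (LSK, control; 111 to 158), and these intervals cover counting error only. With limma the log2 fold change of the mean over populations was -0.40 (95% interval -0.94 to 0.15, adjusted p = 0.699). Over 22 other settings it ranged from -0.59 (without mouse 1 of both genotypes) to -0.11 (edgeR, on reads summed over the gates). Within single populations it was 0.01 in LSK, 0.26 in CMP and -0.48 in GMP, while in MEP Cxadr did not pass the filter. The value of -0.40 thus rests largely on the MEP libraries, whose counts lie near the floor. In LSK the log2 fold change of 0.01 turned negative with TMM scaling (-8.831e-04) and without control mouse 1 (-0.07), 2 (-0.05) or 3 (-0.15) or Cxadr-ko mouse 2 (-0.09) or 3 (-0.33). The part of the gene between the loxP sites is not given in the sources used here, and gene-level counts also take reads outside it, so these values neither bear out nor contradict the genotype labels. The groups are therefore named below as labelled.

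**Figure D1:**
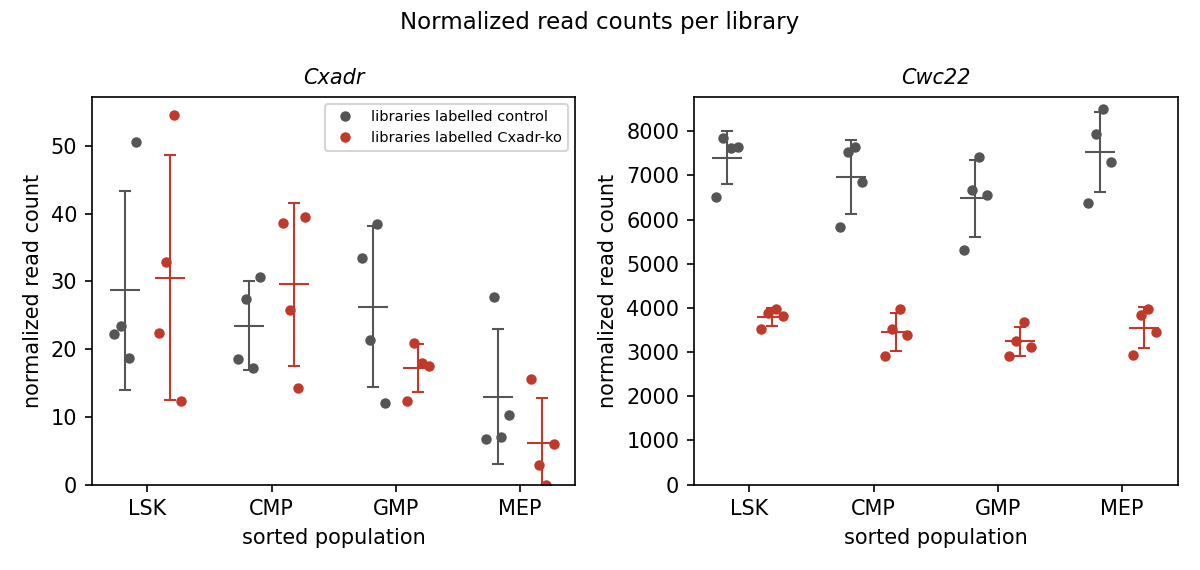
Normalized read count of Cxadr and Cwc22 (vertical axes, starting at 0) in the 4 sorted populations (horizontal axes). Each point is 1 library, grey for control and red for Cxadr-ko, and the bars show mean ± SD of 4 libraries: the Cxadr groups overlap, while the Cwc22 values of the Cxadr-ko libraries lie between 2914 and 3983 and those of the control libraries between 5304 and 8508.

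The sorted populations were then compared with each other in the 4 control mice, each against the mean of the other gates with the mouse as a block. LSK libraries were rich in stem cell and megakaryocyte genes and poor in granule genes. Of 23 stem and multipotent progenitor genes, 22 were higher in LSK, and of 22 granulocyte-monocyte genes 21 were lower. Of 19 megakaryocyte genes 14 were higher and 1 lower. Mmrn1, a platelet granule protein, stood at 2181 ± 386 (SD, n = 4) in LSK against 80.3 ± 19.4 in CMP, 13.6 ± 10.5 in GMP and 85.6 ± 14.5 in MEP (log2 difference 5.67 ± 0.37 (SE), limma adjusted p = 4.3e-08). Elane, neutrophil elastase, was lower in LSK (267 ± 195, n = 4; log2 difference -5.08 ± 0.25 (SE), limma adjusted p = 2.2e-09). Interferon-stimulated genes (31 of 41 higher, 2 lower) and immediate early genes (17 of 21 higher, 1 lower) were also higher in LSK, and mitochondrially encoded genes (9 of 9) lower.

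GMP libraries showed the opposite pattern, with granule genes at their highest. Of the granulocyte-monocyte genes 21 of 22 were higher in GMP, as were 11 of 13 mast cell, basophil and eosinophil genes, and 22 of 23 stem cell genes were lower. Elane reached 55621 ± 16287 (SD, n = 4; log2 difference 5.54 ± 0.25 (SE), limma adjusted p = 1.1e-09), and Prg2, the eosinophil granule major basic protein, 2169 ± 546 (n = 4) against group means of 2.37 to 7.14 elsewhere (log2 difference 9.08 ± 0.67 (SE), limma adjusted p = 1.9e-07). Mitochondrially encoded genes were higher (9 of 9), as were 24 of 38 ribosomal protein and 23 of 38 oxidative phosphorylation genes.

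CMP and MEP libraries lay close together. Of 17218 genes tested, 6560 differed for LSK (3530 higher), 5363 for GMP (2460 higher), 608 for MEP (317 higher), and 62 were higher and 39 lower in CMP. With quantile normalization the higher share of the LSK calls went from 53.8% to 44.0% (3132 higher, 3984 lower) and that of the GMP calls from 45.9% to 51.5%, and with edgeR that of the MEP calls went from 52.1% to 65.5%. Compared directly, CMP and MEP differed in 18 of 15813 genes, against 1027 for GMP and MEP, the pair with the next fewest. In MEP 3 of 17 erythroid genes were higher than the mean of the other gates, and so were 7 of 11 T and NK cell genes and 7 of 13 mast cell, basophil and eosinophil genes, although of the last list Csrp3, at 321, stood below its GMP mean of 561. Between CMP and MEP none of 13 erythroid genes differed: Klf1, an erythroid transcription factor, stood at 58.1 ± 26.1 in CMP and 93.5 ± 8.35 in MEP (SD, n = 4 each; limma adjusted p = 0.373), and Gata1 at 194 ± 54.1 and 274 ± 55.9 (limma adjusted p = 0.402). MEP libraries also held 46861 ± 6659 Mpo (myeloperoxidase) and 8179 ± 975.2 Cd34 counts (n = 4). Both were somewhat lower than in CMP (log2 difference -0.24 for Mpo and -0.27 for Cd34, the latter with limma adjusted p = 0.110). Over all 32 libraries the highest Klf1 value, 221, was in the GMP library of Cxadr-ko mouse 4, and among the control libraries it was 106, in MEP control mouse 1. The lymphoid gene Dntt, terminal transferase, stood at 3297 in LSK, 2040 in CMP, 1614 in MEP and 77.002 in GMP, so that its call in CMP (log2 difference from the mean of the other gates 1.44 ± 0.12 (SE), n = 4, limma adjusted p = 2.1e-04) goes with a still higher LSK value. Il7r, called in MEP against that mean (2.19 ± 0.43, limma adjusted p = 0.0155), stood at 98.4 in MEP, 98.8 in CMP, 51.0 in LSK and 1.75 in GMP. Leaving out any 1 of the 4 control mice left 24 to 50 calls for CMP and 118 to 306 for MEP, while DESeq2 made 384 and 1097.

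**Figure D2:**
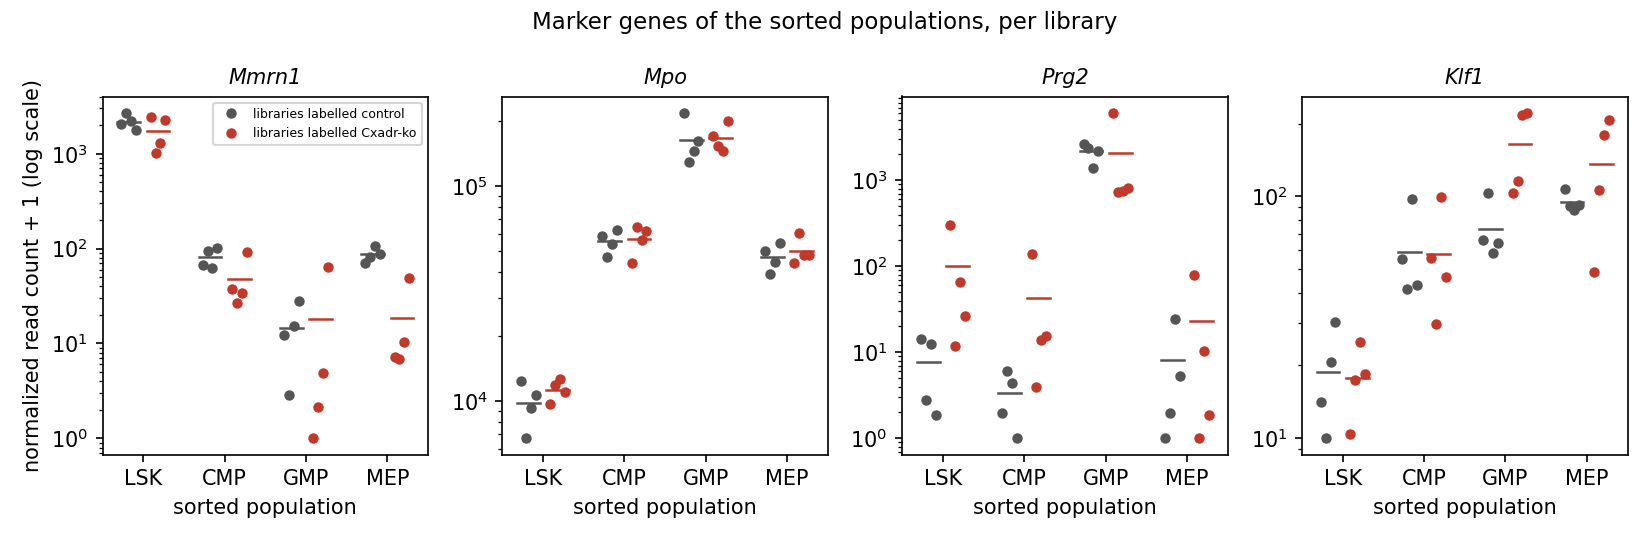
Normalized read count plus 1, on log axes, of Mmrn1, Mpo, Prg2 and Klf1 in each sorted population (horizontal axes). Each point is 1 library, grey for control and red for Cxadr-ko, and lines mark the mean of 4 libraries: Mmrn1 is highest in LSK and Mpo and Prg2 in GMP, while Klf1 reaches no more than 221 and does not set MEP apart.

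The main comparison of the study, Cxadr-ko against control, gave 1 group of genes that was lower in all 4 populations and called in each, but for Gm13696 in GMP. Genes without a call also had lower values in all 4, among them Sdc2 (log2 fold change -1.09 in LSK, -1.08 in CMP, -1.16 in GMP and -1.26 in MEP). Cwc22, a splicing factor that helps to place the exon junction complex, and the predicted protein-coding genes Gm13694, Gm13695 and Gm13696 were each about 0.5 times as abundant in the Cxadr-ko libraries. In the mean over populations Cwc22 fell from 7097 ± 784 to 3514 ± 350 (SD, n = 4 each; log2 fold change -1.01 ± 0.09 (SE), limma adjusted p = 0.00243), Gm13694 from 2611 ± 253 to 1245 ± 136 (-1.07 ± 0.09), Gm13695 from 665 ± 18.7 to 307 ± 34.5 (-1.12 ± 0.09) and Gm13696 from 1620 ± 191 to 770 ± 88.9 (-1.07 ± 0.10). These were the 4 genes called of 18475 tested. The next genes by p, Rab5if, Il1r2 and Rps29, were not called (limma adjusted p = 0.165, 0.185 and 0.185). Cwc22 (ENSMUSG00000027014) lies on chromosome 2 from 77881159 to 77946375, and the predicted genes lie together on it, Gm13695 (ENSMUSG00000096729) from 83967313 to 83969805, Gm13696 (ENSMUSG00000096484) from 83973123 to 83975615 and Gm13694 (ENSMUSG00000096337) from 83978933 to 83981425 (mm10). The predicted genes share at least 98.0% of their 50-base words with each other, and 46.6% to 46.7% of them with Cwc22, so how reads were divided among them is uncertain. Of the words of Cwc22, 16.4% to 16.5% occur in a predicted gene, so less of its sequence is open to such sharing.

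The log2 fold change of Cwc22 was -0.96 ± 0.07 (SE) in LSK, -1.01 ± 0.11 in CMP, -0.995 ± 0.114 in GMP and -1.08 ± 0.11 in MEP, with limma adjusted p of 3.1e-04, 0.00688, 0.0233 and 0.0175. Gm13694 and Gm13695 were called in every population and Gm13696 in every one but GMP (log2 fold change -0.95 ± 0.14 (SE), limma adjusted p = 0.169). The test of a difference between populations gave an adjusted p of 0.920 for Cwc22. Without 1 mouse, the calls ranged from 4 to 6 in the mean over populations, where all 4 genes kept their calls, but from 0 to 5 in CMP, 0 to 2 in GMP and 0 to 4 in MEP. The log2 fold change of Cwc22 itself stayed, over 23 other settings, at -1.09 to -0.93 in CMP and in GMP and at -1.16 to -0.996 in MEP. Some of these settings, such as robust variance or the cohort term, cannot move a fold change. In place of the 4 calls in the mean over populations, a fit of all 32 libraries gave 53. DESeq2, on reads summed over the gates of each mouse and so on another measure, gave 76.

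In LSK, the population that holds the stem cells, 3 further genes were called beside these 4 (7 of 16166 tested). Pmaip1, which encodes the pro-apoptotic protein Noxa, rose from 477 ± 91.2 to 1024 ± 149 (SD, n = 4 each; log2 fold change 1.11 ± 0.15 (SE), limma adjusted p = 0.0348), and Plaur, the urokinase receptor, from 655 ± 45.4 to 1023 ± 69.1 (0.64 ± 0.08, limma adjusted p = 0.0190). Rbm45, an RNA-binding protein whose gene lies on chromosome 2 from 76369984 to 76383768, fell from 385 ± 19.3 to 221 ± 19.5 (-0.80 ± 0.10, limma adjusted p = 0.0190). The next genes by p were Cd53, a leukocyte tetraspanin (log2 fold change 0.57 ± 0.08), Plac8 (0.48 ± 0.07) and Pgr, the progesterone receptor (-0.97 ± 0.15), which were not called (limma adjusted p = 0.0594, 0.0675 and 0.0993). The calls of Pmaip1, Plaur and Rbm45 were lost in 10, 8 and 10 of 23 other settings, among them the mouse number as a replicate block (4 calls, limma adjusted p = 0.0689 for each of the 3).

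Among the gene lists in LSK, 12 of 26 were called by camera with its preset correlation. NF-kB and TNF response genes had higher values in 18 of 21 (median log2 fold change 0.51, limma camera adjusted p = 9.6e-08, adjusted p = 0.457 with an estimated correlation). The chemokine genes Cxcl10 and Ccl4 among them stood at 118 ± 14.7 and 1233 ± 364 in control and at 398 ± 208 and 2730 ± 892 in Cxadr-ko libraries (SD, n = 4 each). Granulocyte-monocyte genes had higher values in 19 of 21 (median 0.33, limma camera adjusted p = 2.7e-06), among them Plac8 at 8126 ± 349 and 11348 ± 1137. Dendritic cell genes had higher values in 11 of 12 (median 0.69, limma camera adjusted p = 2.2e-04). Both had an adjusted p = 0.457 with an estimated correlation. Of these 3 lists 5, 4 and 0 members passed when adjusted over the list alone, and none over all genes. Megakaryocyte genes had lower values in 15 of 18 (median -0.28, limma camera adjusted p = 0.00346, adjusted p = 0.457 with an estimated correlation, 4 adjusted over the list alone and none over all genes). Of these the transcription factor gene Gfi1b stood at 840 ± 31.8 and 597 ± 75.3 (SD, n = 4 each). Stem cell genes had lower values in 18 of 23 (median -0.16, limma camera adjusted p = 0.00575, adjusted p = 0.574 with an estimated correlation, 0 adjusted over the list alone), with Hlf at 1418 ± 71.4 and 1086 ± 216. Without 1 mouse the medians of these lists moved by over 1.5 times, those of NF-kB genes to 0.31 (Cxadr-ko 3) and 0.34 (Cxadr-ko 4), of granulocyte-monocyte genes to 0.15 (control 2) and of dendritic cell genes to 0.44 (control 2) and 0.36 (Cxadr-ko 4). The median of stem cell genes moved to -0.30, -0.10, -0.10 and -0.25 without Cxadr-ko mouse 1, 2, 3 or 4, and that of megakaryocyte genes by less than 1.5 times.

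The other list calls in LSK were also lost with an estimated correlation. Ribosomal protein genes had higher values in 35 of 38 in LSK (median 0.12, limma camera adjusted p = 6.7e-11), oxidative phosphorylation genes in 32 of 38 (median 0.10, adjusted p = 9.6e-08) and mitochondrially encoded genes in 9 of 9 (median 0.27, adjusted p = 1.7e-04). With an estimated correlation their adjusted p was 0.530, 0.457 and 0.530, and 0, 0 and 1 members passed when adjusted over the list alone. Quantile normalization lowered the medians of the ribosomal and oxidative phosphorylation genes to 0.05 and 0.06. Mature neutrophil genes had higher values in 10 of 11 (median 0.83, limma camera adjusted p = 0.00611) and immediate early genes in 17 of 22 (median 0.24, adjusted p = 0.00696). Lymphoid progenitor genes had higher values in 13 of 14 (median 0.26, limma camera adjusted p = 0.00142) and mast cell, basophil and eosinophil genes in 5 of 6 (median 0.47, adjusted p = 0.0291). With an estimated correlation the adjusted p of these 4 lists was 0.576, 0.576, 0.457 and 0.530, and 1, 2, 2 and 2 members passed when adjusted over the list alone. Retnlg, a neutrophil gene, stood at 18.3 ± 8.39 and 103 ± 43.5, Atf3 at 1013 ± 331 and 2051 ± 298, and Satb1 at 761 ± 48.4 and 1014 ± 136 (n = 4 each, none called over all genes). The camera call of stem cell genes was lost without Cxadr-ko mouse 3 (limma camera adjusted p = 0.113), that of mature neutrophil genes without Cxadr-ko mouse 2 (0.128), that of immediate early genes without control or Cxadr-ko mouse 4 (up to 0.122). That of mast cell, basophil and eosinophil genes was lost without control mouse 2 or Cxadr-ko mouse 1 or 3 (up to 0.197). Medians that moved by over 1.5 times with the call kept were those of ribosomal protein genes (0.08 without control 1), mitochondrially encoded genes (0.16 without control 1, 0.17 without Cxadr-ko 4) and lymphoid progenitor genes (0.13 without control 3, 0.05 without Cxadr-ko 3). So did those of neutrophil genes (0.47 without control 1) and immediate early genes (0.38 without control 2, 0.37 without Cxadr-ko 1). The LSK libraries of mouse 1 held the most immunoglobulin transcripts, 12.5% of reads in the control and 5.25% in the Cxadr-ko mouse, and without both of these mice 13 genes were called. The LSK count was 4, with Pmaip1, Plaur and Rbm45 no longer called, without any 1 of control mice 2, 3 or 4 or Cxadr-ko mice 2 or 3. These 3 genes were also not called without Cxadr-ko mouse 4 (6 calls), nor Rbm45 without control mouse 1 (8 calls), while 27 genes were called without Cxadr-ko mouse 1 and 95 with DESeq2.

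In CMP the 4 genes of the Cwc22 group were the only ones called of 15737. Mature neutrophil genes had higher values in Cxadr-ko in 14 of 15 (median log2 fold change 1.84, limma camera adjusted p = 1.6e-08, adjusted p = 0.457 with an estimated correlation), and the median was 0.97 without control mouse 1 and 1.18 without Cxadr-ko mouse 2. Among them Chil3 stood at 190 ± 158 and 1044 ± 1148 and Ltf, lactoferrin, at 299 ± 220 and 1430 ± 1562 in control and Cxadr-ko libraries (SD, n = 4 each). Mitochondrially encoded genes had higher values in 9 of 9 (median 0.28, limma camera adjusted p = 1.6e-08), mt-Nd1 standing at 12892 ± 757 and 16661 ± 879. The CMP library of control mouse 1 had the lowest share of mitochondrial reads of the controls (1.64% against 2.01% to 2.05%), and without it the median was 0.20 (limma camera adjusted p = 1.1e-06). The adjusted p with an estimated correlation was 0.457 for both lists, and 0 and 5 members passed when adjusted over the list alone. B cell genes had higher values in 7 of 8 (median 0.59, limma camera adjusted p = 8.4e-04, 4 adjusted over the list alone), with Cd79a at 18.2 ± 12.3 and 77.5 ± 36.2 and a median of 1.11 without Cxadr-ko mouse 4. Stem cell genes had lower values in 17 of 20 (median -0.34, limma camera adjusted p = 8.4e-04, 1 adjusted over the list alone), with Tek at 173 ± 16.4 and 104 ± 23.5. Both had an adjusted p = 0.457 with an estimated correlation, and no member of these 4 lists passed over all genes. Immunoglobulin transcripts took 0.287% of the reads of the CMP library of Cxadr-ko mouse 1 and at most 0.139% of any other CMP library.

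Of the other lists called in CMP with the preset correlation, all of them lost with an estimated one, ribosomal protein genes had higher values in 35 of 38 (median 0.09, limma camera adjusted p = 1.6e-07), oxidative phosphorylation genes in 33 of 38 (median 0.09, adjusted p = 9.6e-08) and G1/S genes in 22 of 24 (median 0.10, adjusted p = 8.4e-04). Glycolysis and hypoxia genes had higher values in 16 of 21 (median 0.10, limma camera adjusted p = 0.00161) and granulocyte-monocyte genes in 17 of 22 (median 0.20, adjusted p = 0.00251). So had NF-kB and TNF response genes in 16 of 21 (median 0.17, adjusted p = 0.0371). T and NK cell genes had higher values in 9 of 9 (median 0.83, limma camera adjusted p = 0.0154). Megakaryocyte genes had lower values in 11 of 18 (median -0.17, adjusted p = 0.0457). With an estimated correlation the adjusted p of these 8 lists lay between 0.457 and 0.530. Quantile normalization lowered the medians of ribosomal protein genes to 0.01, of oxidative phosphorylation genes to 0.04, of G1/S genes to 0.06 and of granulocyte-monocyte genes to 0.11. Adjusted over the list alone, 6 ribosomal protein genes and 2 megakaryocyte genes passed, among the latter Thbs1 at 96.0 ± 23.9 and 38.8 ± 16.3 (n = 4 each), and no member of the other 6 lists did. Beside the Cwc22 group the genes of lowest p were mt-Nd1, Fcmr (2.34 ± 2.67 and 33.5 ± 12.2), Rgs10 and Bmpr1a (47.0 ± 6.95 and 15.3 ± 4.05), none called (limma adjusted p = 0.192 to 0.396). Without 1 mouse the limma camera calls lost in CMP were those of granulocyte-monocyte genes (control 2, adjusted p = 0.0524) and NF-kB and TNF response genes (control 3 or 4 or Cxadr-ko 2 or 4, up to 0.354). Also lost were those of T and NK cell genes (control 2 or 3 or Cxadr-ko 1 or 2, up to 0.399) and megakaryocyte genes (control 3 or 4 or Cxadr-ko 1 or 3, up to 0.310). Other medians that moved by over 1.5 times were those of G1/S genes (0.16 without Cxadr-ko 2), granulocyte-monocyte genes (0.12 without Cxadr-ko 3) and megakaryocyte genes (-0.10 without Cxadr-ko 2, -0.27 without Cxadr-ko 4). With DESeq2 there were 39 calls and with a term for mouse 1 against the others 9. No call was left without control mouse 3, and without control mouse 2 or 4 only that of Gm13695.

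In GMP 3 genes of 15593 were called, Cwc22, Gm13694 and Gm13695. Of the dendritic cell and mast cell lists no gene was called: H2-Ab1, an MHC class II chain, stood at 4169 ± 1929 and 8550 ± 1624, H2-Aa at 1377 ± 654 and 3064 ± 815, and the IgE receptor chain Fcer1a at 827 ± 124 and 1299 ± 204 (SD, n = 4 each; limma adjusted p = 0.873 for each). All list calls in GMP were lost with an estimated correlation. Dendritic cell genes had higher values in 10 of 12 (median log2 fold change 0.42, limma camera adjusted p = 8.4e-04) and mast cell, basophil and eosinophil genes in 9 of 13 (median 0.31, adjusted p = 0.0149). B cell genes had higher values in 7 of 7 (median 1.03, limma camera adjusted p = 3.8e-05) and erythroid genes in 10 of 11 (median 0.84, adjusted p = 0.00209). Each of these 4 lists had an adjusted p = 0.457 with an estimated correlation, and 4, 2, 1 and 1 members passed when adjusted over the list alone. The erythroid gene Klf1 stood at 72.0 ± 20.7 and 163 ± 63.5, and Fcrla, a B cell gene, at 7.96 ± 12.7 and 53.8 ± 33.9 (SD, n = 4 each). Immunoglobulin transcripts took 1.15% of the reads of Cxadr-ko mouse 2 and at most 0.0678% of any other GMP library. NF-kB and TNF response genes had higher values in 15 of 21 (median 0.20, limma camera adjusted p = 0.00332) and cholesterol synthesis genes in 14 of 19 (median 0.19, adjusted p = 0.0125). Mature neutrophil genes had higher values in 13 of 15 (median 0.80, limma camera adjusted p = 0.0215) and immediate early genes in 16 of 21 (median 0.26, adjusted p = 0.0219). With an estimated correlation their adjusted p was 0.457, 0.487, 0.660 and 0.660, and 0 of their members passed when adjusted over the list alone. Without control mouse 1 the neutrophil median fell to -0.10 (limma camera adjusted p = 0.856) and without Cxadr-ko mouse 2 to 0.01 (0.997). Other limma camera calls lost in GMP without 1 mouse were those of NF-kB (control 1, adjusted p = 0.0790), cholesterol (control 3 or Cxadr-ko 2, up to 0.0659), erythroid (Cxadr-ko 3 or 4, up to 0.118), mast cell (Cxadr-ko 1, 0.08996) and immediate early genes (control 1 or 4 or Cxadr-ko 2, 3 or 4, up to 0.675). Medians also moved by over 1.5 times for dendritic cell genes (0.22, 0.22, 0.12 and 0.67 without control 3 or Cxadr-ko 1, 3 or 4), B cell genes (0.37 without Cxadr-ko 2), erythroid genes (1.32 and 0.28 without Cxadr-ko 1 or 2) and mast cell genes (0.13 without Cxadr-ko 4). So they did for NF-kB genes (0.39 and 0.37 without control 2 or Cxadr-ko 1), immediate early genes (0.50 and 0.48 without the same mice) and cholesterol genes (0.10 and 0.31 without control 4 or Cxadr-ko 3). No call was left in GMP without any 1 of control mice 2, 3 or 4 or Cxadr-ko mice 1, 2 or 4. The log2 fold changes moved little over 23 other settings (Cwc22 -1.09 to -0.93, Gm13694 -1.13 to -0.97, Gm13695 -1.13 to -0.99), though some of these cannot move them. The call of Gm13695 was lost without control mouse 1 or Cxadr-ko mouse 3 (2 calls left), and 1 call was left without mouse 1 of both genotypes. A fit of all 32 libraries gave 11 calls and DESeq2 14, that of Gm13695 not among the latter.

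In MEP the 4 genes of the Cwc22 group were called of 15812. Dtnbp1 was next (856 ± 41.1 and 543 ± 31.1, SD, n = 4 each; log2 fold change -0.66 ± 0.09 (SE), limma adjusted p = 0.122). All list calls in MEP were lost with an estimated correlation. Dendritic cell genes had higher values in 11 of 13 (median 0.90, limma camera adjusted p = 2.8e-05), with H2-Ab1 at 6532 ± 1629 and 13838 ± 4426. Stem cell genes had lower values in 16 of 22 (median -0.25, limma camera adjusted p = 0.00937), and megakaryocyte genes in 14 of 18 (median -0.29, adjusted p = 0.0139), with Mmrn1 at 85.6 ± 14.5 and 17.5 ± 20.7. Each of these 3 lists had an adjusted p = 0.457 with an estimated correlation, and 5, 0 and 1 members passed when adjusted over the list alone. G1/S genes had higher values in 16 of 24 (median 0.10, limma camera adjusted p = 0.00290), with Rrm2, which encodes a subunit of ribonucleotide reductase, at 2469 ± 379 and 3420 ± 99.5. G2/M genes had higher values in 19 of 25 (median 0.09, limma camera adjusted p = 0.0245) and oxidative phosphorylation genes in 26 of 38 (median 0.06, adjusted p = 0.0125). So had glycolysis and hypoxia genes in 16 of 21 (median 0.09, limma camera adjusted p = 0.0139) and cholesterol synthesis genes in 16 of 19 (median 0.15, adjusted p = 0.0371). Immediate early genes had lower values in 16 of 21 (median -0.14, limma camera adjusted p = 0.0330). With an estimated correlation the adjusted p of these 6 lists lay between 0.457 and 0.628, and of their members Rrm2 alone passed when adjusted over the list alone. Under quantile normalization the G1/S median was 0.07 and that of oxidative phosphorylation genes 0.02. The limma camera calls lost in MEP without 1 mouse were those of megakaryocyte (Cxadr-ko 1, adjusted p = 0.161), G1/S (control 3, 0.0642) and glycolysis genes (control or Cxadr-ko 2, up to 0.117). Also lost were those of G2/M (control 3 or Cxadr-ko 1, 3 or 4, up to 0.377), cholesterol (control 2, 3 or 4 or Cxadr-ko 3 or 4, up to 0.130), immediate early (control 2 or 3 or Cxadr-ko 1, up to 0.767) and oxidative phosphorylation genes (control 2 or 3 or Cxadr-ko 1, up to 0.139). Other medians that moved by over 1.5 times were those of stem cell genes (-0.14 without control 1), megakaryocyte genes (-0.50 without Cxadr-ko 4), cholesterol genes (0.25 and 0.27 without control 1 or Cxadr-ko 2), immediate early genes (-0.23 without control 4), G1/S genes (0.07 without control 4) and G2/M genes (0.20 without Cxadr-ko 2). No call was left in MEP without any 1 of control mice 2, 3 or 4, and 2 were left without control mouse 1 or Cxadr-ko mouse 1 or 4. Without Cxadr-ko mouse 2 those of Gm13694 and Gm13696 were lost (3 calls). DESeq2 gave 24 calls, a fit of all 32 libraries 8, and the fit without mouse 1 of both genotypes 1.

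Over the 4 populations 41 of 100 list tests were called with the preset correlation, 34 higher and 7 lower in Cxadr-ko. Each of the 34 other splits of the 8 mice into 4 and 4 also gave list calls with it, from 7 to 38. Between the genotypes none was called with an estimated correlation (9 at an unadjusted p under 0.05, smallest adjusted p = 0.457) or by fry (smallest adjusted p = 0.0850). With fry's mixed test, which takes no account of direction, 4 lists passed: megakaryocyte genes in LSK and ribosomal protein genes in CMP (limma fry adjusted p = 0.0369 each), and erythroid genes in LSK and B cell genes in CMP (0.0412 each). Interferon-stimulated genes were not called in any population (limma camera adjusted p = 0.691 in LSK, 0.166 in CMP, 0.272 in GMP and 0.501 in MEP). Neither were tight junction and CAR-family adhesion genes (limma camera adjusted p = 0.617, 0.548, 0.308 and 0.888), heme synthesis genes (0.956, 0.501, 0.229 and 0.691) or unfolded protein response genes (0.794, 0.603, 0.109 and 0.432). The p53 target genes (0.397, 0.382, 0.351 and 0.837), of which Pmaip1 was called in LSK, and the chemokine receptor and niche adhesion genes (0.888, 0.195, 0.954 and 0.268) were not called either. Median, mean and test did not all have 1 sign for interferon-stimulated genes in LSK and GMP, p53 targets in LSK, tight junction genes in LSK and CMP, erythroid, B cell and chemokine receptor genes in LSK, lymphoid genes in GMP, and unfolded protein response and NF-kB genes in MEP, none of them called. Among the chemokine receptor and niche adhesion genes Kit, the stem cell factor receptor, stood at 1853 ± 72.1 and 1540 ± 37.3 in the mean over populations (SD, n = 4 each; log2 fold change -0.26 ± 0.05 (SE), limma adjusted p = 0.369). Stromal and endothelial genes could be tested in LSK only (limma camera adjusted p = 0.268), and macrophage genes had at most 4 members above the filter in a population.

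**Figure D3:**
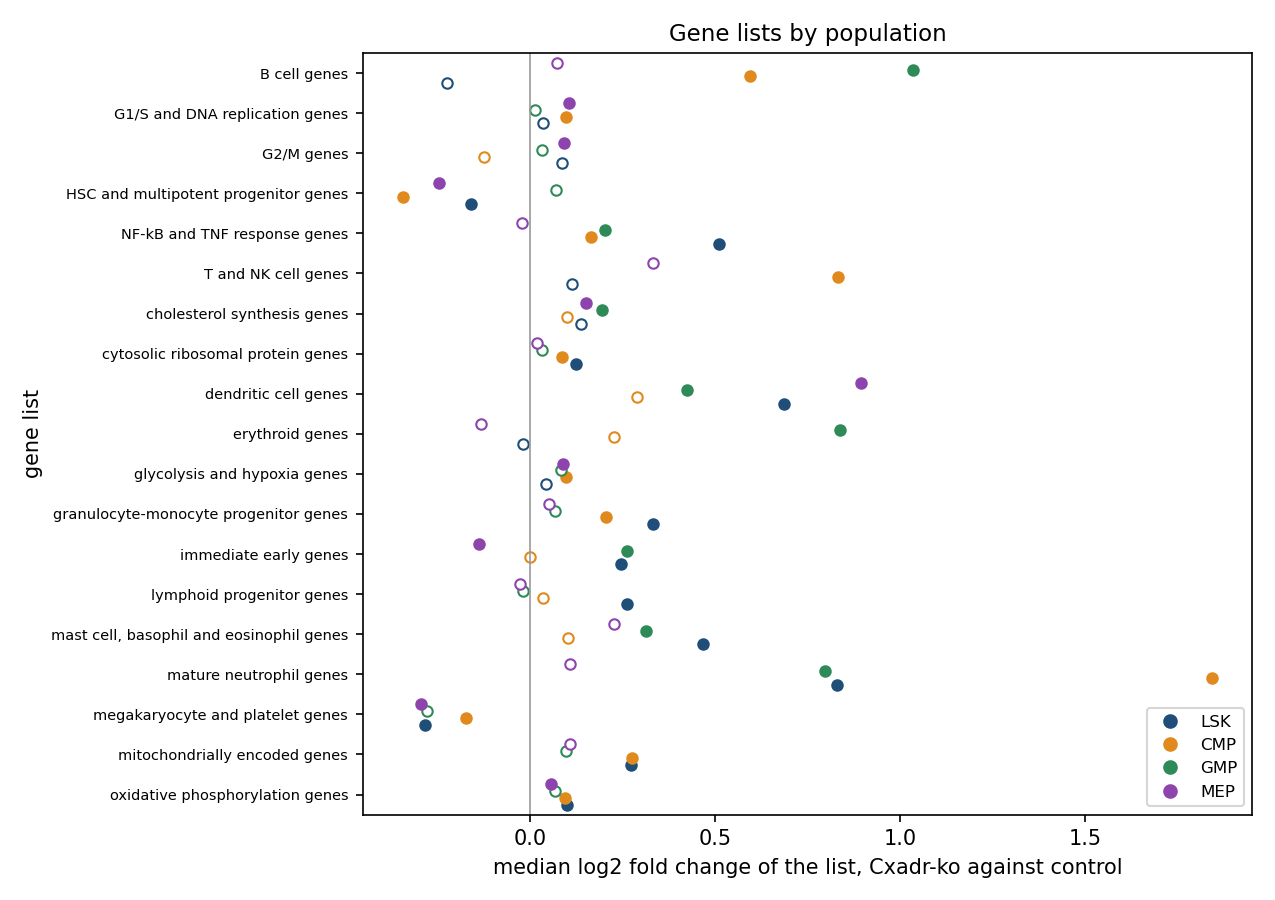
Median log2 fold change, Cxadr-ko against control (horizontal axis), of each gene list called by camera with its preset correlation in at least 1 population (vertical axis). Each point is 1 list in 1 population, coloured by population, filled where the list was called with the preset correlation and open where not; mature neutrophil genes in CMP lie highest, at 1.84, and no list was called with an estimated correlation.

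Whether the genotype difference itself varied between populations was tested over all 32 libraries with limma. No gene of 18475 was called (1082 at an unadjusted p under 0.05; 0 calls with edgeR and 23 with DESeq2). The genes of lowest p were Wrap73, with log2 fold changes of -0.12 in LSK, -0.74 in CMP, 0.31 in GMP and 0.28 in MEP, and Rab37, with -0.28, -0.08, 0.78 and -0.09 (limma adjusted p = 0.0950 for both). Plac8 followed (0.48, 0.21, 0.06 and 0.14; limma adjusted p = 0.366). Without Cxadr-ko mouse 1 there were 3 calls, and without the filter on low values 1.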

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

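Of the tests in this part, those of the linked stretch of chromosome 2, of the loss of Cxadr, of reads shared between the predicted genes, of differences between individual mice, of mice 2 to 4 alone, of the 4 explanations for the MEP libraries and of the splits by mouse 1 were chosen after the result was seen, and so was the correction for transcript length as a setting.

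Within each group of 4 libraries, 5 quality measures and 8 genes were screened for a library far from the other 3. Of 104 groups and measures 18 had one, where chance gives about 1 in 20, or 5.20. Immunoglobulin transcripts took 12.5% of the reads of LSK control mouse 1 (0.154% to 1.202% in the others), 0.287% of CMP Cxadr-ko mouse 1 (0.0456% to 0.0616%), 0.0678% of GMP control mouse 1 (0.0273% to 0.0321%), 1.15% of GMP Cxadr-ko mouse 2 (0.0361% to 0.0609%) and 0.484% of MEP control mouse 2 (0.0464% to 0.0546%). The most abundant gene took 4.66% of the reads of LSK control mouse 1 (0.782% to 0.827%) and 1.80% of LSK Cxadr-ko mouse 1 (0.946% to 1.07%), Igkc in both, and 0.769% of CMP control mouse 1 (0.961% to 0.996%). Mitochondrial transcripts took 1.64% of CMP control mouse 1 (2.01% to 2.05%) and 1.67% of MEP control mouse 1 (2.36% to 2.39%).

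Among the genes, Cxadr stood at 50.5 in LSK control mouse 4 (18.7 to 23.3 in the others) and Cwc22 at 6508 in LSK control mouse 1 (7619 to 7843). Gm13696 stood at 1334 in CMP control mouse 1 (1687 to 1747), Gm13694 at 995 (1298 to 1359) and Gm13695 at 266 (332 to 337) in CMP Cxadr-ko mouse 1, and Gm13695 at 726 in MEP control mouse 3 (627 to 637). Rbm45 stood at 407 in GMP control mouse 1 (297 to 314) and Pmaip1 at 675 in GMP control mouse 3 (895 to 925).

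Cwc22, Gm13694, Gm13695 and Gm13696 were lower in all 4 populations of the libraries labelled Cxadr-ko, though Gm13696 was not called in GMP. A difference confined to mouse 1 of each genotype is argued against, since in mice 2 to 4 the weakest of the 4 genes fell by 1.03 (log2, upper 95% limit -0.89), whereas a term for mouse 1 decides nothing (Cwc22 at -1.01), as 1 of 4 mice in each genotype cannot move the difference. Reads shared between the predicted genes may account for their moving alike (at least 98.0% of their 50-base words in common). Sharing with Cwc22 stays open at 46.6%, between the bounds of 50% and 10% set beforehand. In the other direction 16.4% to 16.5% of the Cwc22 words occur in a predicted gene, so most of its annotated sequence lies outside such sharing. Differences between individual mice unrelated to the deletion may also be the cause, since 3 of 34 other splits of the mice had a gene called in the same direction in every population. Each of these 3 splits had mouse 1 of both genotypes on 1 side, and none of the 19 other splits that part them, as the real one does, had such a gene. A linked stretch of chromosome 2 stays open. Of its genes 9.92% had an unadjusted p under 0.05 (7 lower, 6 higher), against 7.91% of all genes tested. That share is reached by 26.2% of 503 windows, but it gives no weight to strong changes of single genes. Ranked by p, Rbm45 and Tfpi came first, both lower (log2 fold change of the mean -0.63 and -0.46). Ube2l6 and Rpl9-ps7 followed, both higher (0.31 and 0.20). Rbm45 was lower in LSK (-0.80), CMP (-0.64), GMP (-0.40) and MEP (-0.68), though called in LSK only. A change in copy number and DNA linked to Mx1-Cre were not tested. The loss of Cxadr, the explanation the design names, stays open too, since it is confounded with the groups and the log2 fold change of Cxadr itself was -0.40 (95% interval -0.94 to 0.15). That value rests largely on MEP libraries with counts near the floor.

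The libraries labelled MEP lay close to those labelled CMP and were low in erythroid genes, although MEP had the highest erythroid median of its mouse in 3 of 8 mice and MEP control mouse 3 the highest of all libraries (4.34 on the log2 scale). A first test, of an exchange with any gate, met its bound: a median of the erythroid genes over 1 (log2) above the MEP library of the same mouse was to count for an exchange, and in GMP Cxadr-ko mouse 4, 1 of 24 libraries compared, it was 2.01 above. That outcome was set to undecided only after it was seen, because 12 of the 27 erythroid genes had a mean under 10 over the libraries, and the next 2 tests were added after it. An exchange with LSK or GMP is argued against, since in 8 of 8 mice the LSK library was highest in stem cell genes and the GMP library in granulocyte-monocyte genes. One with CMP stays open, since over 15 erythroid genes with a mean of at least 10 the CMP median lay 0.11 (log2) above MEP (95% interval -0.35 to 0.58, 8 mice). A gate that held cells like those of the CMP gate could account for the pattern, as CMP and MEP differed in 14 genes in the Cxadr-ko mice too, against 519 for GMP and MEP, the pair with the next fewest, and no biological explanation was tested.

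Of 100 list tests 41 were called with the preset correlation and 0 with an estimated one (9 at an unadjusted p under 0.05) or by fry. Transcript length is argued against as the cause, since 39 of the 41 calls were left after correction for it. A difference confined to mouse 1 of each genotype is argued against too, since 37 were left in mice 2 to 4, whereas a term for mouse 1 decides nothing (41 left), as the genotypes hold equal numbers of it. Correlation of genes within lists, or other differences between the mice, could account for many of these calls. Each of the 34 other splits of the mice also gave list calls with the preset correlation, from 7 to 38. The genotype stays open, since no test of these data separates it from other differences between the mice.

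Whether chance can be excluded was judged from the 35 splits of the 8 mice into 4 and 4, each count of splits including the real one. Over all of these it was excluded in MEP (1 split with as many genes, 4 real, highest other 2), and so it was for the list calls (1 split, 41 real, highest other 38). However, the 20 splits that part mouse 1 of the 2 genotypes, as the real one does, cannot decide this. The real split alone is 5% of them, so a share under 5% was out of reach. Chance was not excluded in LSK (2 splits, 7 real, highest other 10), CMP (2 splits, 4 real, highest other 4) or GMP (2 splits, 3 real, highest other 3). Nor was it in the mean over populations (3 splits, 4 real, highest other 5) or for the difference between populations (35 splits, 0 real, highest other 6). The other splits with as many calls included genes that part the mice in every population, Hist1h2an in LSK and G530011O06Rik and Gm47283 in CMP and GMP. A count of calls does not test whether the fall of the Cwc22 group itself arose by chance. In LSK, CMP, GMP and the mean, each other split with as many genes had mouse 1 of both genotypes on 1 side, and these 2 animals resembled each other (correlation 0.129 to 0.501), while the 19 other splits that part them as the real one does called 0 genes there with limma and at most 1 in MEP. The 100 permutations of the gates within control mice also include the real one. Only the real one gave as many genes as 6560 for LSK (highest other 3301), 5363 for GMP (highest other 1) and 608 for MEP (highest other 8), which is under 5% of them. Permuted labels mostly mix libraries of unlike gates, which leaves few calls. The MEP result therefore does not show that MEP is set apart from CMP, from which it differed directly in 18 genes. For CMP 2 gave as many as the real 62 higher and 39 lower genes (highest other 1320), which is under 5% of the permutations. That other permutation gave the label CMP to the LSK library in 3 of 4 mice, which points to a structure of the samples.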

How the results depend on the processing

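Leaving out mouse 1 of both genotypes was chosen after the data had been seen, and the other settings here before. Over 115 pairs of a named gene and a comparison, 2453 alternative values had the direction and side of the threshold reported, 87 lost a call, 78 gained one and 6 turned their direction. Most of these pairs were not called to begin with, so that the side reported mostly meant no call. Some settings cannot change a fold change and bear on the call only. These are no filter, robust variance, sex-linked genes left out, the replicate block, the cohort term and the fit of all 32 libraries. The 87 lost calls were those of the Cwc22 group in CMP, GMP and MEP and of Pmaip1, Plaur and Rbm45 in LSK. The 6 that turned were those of Cxadr in LSK, where 0.01 became -8.831e-04 with TMM and -0.07, -0.05, -0.15, -0.09 and -0.33 without control mouse 1, 2 or 3 or Cxadr-ko mouse 2 or 3 (range -0.33 to 0.36). With DESeq2 on recovered reads the calls were 95 in LSK, 39 in CMP, 14 in GMP and 24 in MEP. There were 76 in place of the mean over populations, with the reads of each mouse summed over the gates. The difference between populations had 23, the CMP gate 384 and the MEP gate 1097. In a fit of all 32 libraries the calls were 11 in GMP, 8 in MEP and 53 in the mean. The cohort term gave 9 in CMP. With the mouse number as a replicate block, although the numbers pair no animals, LSK had 4. Without mouse 1 of both genotypes LSK had 13, GMP 1 and MEP 1. Without the low-value filter there was 1 call for the difference between populations, 65 for the CMP and 342 for the MEP gate. With no replicate block these gates had 34 and 197, and in the Cxadr-ko mice 24 and 98. Of the lists 0 were called with an estimated correlation and 0 by fry. Without 1 mouse at a time the counts ranged from 4 to 27 in LSK, 0 to 5 in CMP, 0 to 2 in GMP, 0 to 4 in MEP, 4 to 6 in the mean, 0 to 3 for the difference between populations, 24 to 50 for the CMP gate, 118 to 306 for the MEP gate, 3610 to 4674 for GMP, 4949 to 5549 for LSK and 35 to 47 for the lists. Beyond the fewer mice or genes of some settings, the cause was not tested. The term for sex was not run, since every library had Xist and at most 8 reads of Ddx3y, Eif2s3y, Kdm5d and Uty together. Depth limits what can be said of Cxadr, with 25 to 133 reads per group.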

Other observations

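All tests of other splits in this part were chosen after the result was seen, and no group below was defined by the study.

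For 4 genes the mice fell into high and low ones, alike in all 4 populations of each mouse. G530011O06Rik (X chromosome, 169975043 to 169978917) stood at a mean of 109 to 526 over the gates in control mice 1 and 2 and Cxadr-ko mice 1 and 3, and at 0.204 to 0.538 in the other 4 mice. Gm47283 (Y chromosome in the annotation, 90784738 to 90816465), in the same mice, stood at 2112 to 5652 against 100.5 to 173, while Ddx3y, Eif2s3y, Kdm5d and Uty together had at most 8 reads in any library. Gm42047 (chromosome 8, 121833247 to 121841178) stood at 78.7 to 209 in control mice 2, 3 and 4 and Cxadr-ko mouse 4 and at 0.230 to 0.476 in the others. Hist1h2an, a histone gene (chromosome 13, 21786826 to 21787218), stood at 668 to 1104 in control mouse 2 and Cxadr-ko mice 2, 3 and 4 and at 164 to 204 in the others. These values belong to 4 genes found in 3 of 34 other splits of the 8 mice, and they may come from inherited differences between the animals, a hypothesis for which the DNA of the mice was not analysed here.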
